A study of Sus scrofa with 4 samples.

How the data were processed

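Total RNA was extracted with Trizol from porcine ovarian granulosa cells and kept for library construction at an RNA integrity number above 8, and libraries followed a standard Illumina protocol, per the labels' protocols. The cells came from antral follicles, and the cells left after flow cytometry were grouped by the ratio of cells in G0/G1, per the series' design text. The authors deposited 1 table of whole-number read counts per gene symbol, with 1 column per library. Reads were aligned with HISAT2 to the pig assembly Sscrofa11.1, per the submitters' processing notes. The read counter, the annotation release, the strand setting and any filter are not given in the sources used here, so reads shared by near-identical genes or by genes on opposite strands may be split in ways that cannot be told. The deposited counts are whole numbers whose totals differ between libraries, and they were used as raw counts.

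The table has 29884 rows, of which 29862 match a symbol of the RefSeq annotation of Sscrofa11.1, which gave the coordinates. The 22 without a match are mitochondrial RNA names. All 4 columns were mapped to a sample by its title. Replicate numbers follow the order in which the samples are listed, and they pair nothing. Library totals ran from 27442850 to 32674921. Each library's share of mitochondrially encoded counts has a 95% Wilson interval, and a count of 0 was read as an upper limit of 3 counts. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

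High G0/G1 was compared with low G0/G1 in all 4 libraries with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, estimateDisp, and glmQLFit and glmQLFTest with their defaults), with no covariate and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Of 20394 genes with a count, 14352 were tested. The common biological coefficient of variation was 0.371, and the quasi-likelihood fit had 2 residual and 3.20 prior degrees of freedom. Log2 fold changes are high minus low, and the standard error is the absolute log2 fold change over the root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM values a prior count of 2.

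Gene lists were written before the data were examined, 27 in all, of which 26 had 3 or more tested members. They cover S phase, G2/M, cell cycle inhibitors, FOXO targets, hypoxia, apoptosis, autophagy, endoplasmic reticulum stress, granulosa functions, cholesterol, oxidative phosphorylation, matrix, interferon, immediate early and heat shock genes, markers of other cell types, and mitochondrial and ribosomal genes. Each was tested with limma 3.58.1's camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the 26 lists. Camera with an estimated correlation and fry were the alternatives. Under the estimated correlation no list had an adjusted p under 0.880, so that test made none of the 7 calls. It also missed a list that was shifted in simulation, so its missing calls do not show that a list is unchanged. Members were also counted by their edgeR p, over all genes and adjusted over the list alone.

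Genes are named by a rule fixed before the data were examined. It takes FOXO1, TP53INP1, CDKN1A and HIF1A whatever their values. It then takes the 12 largest changes per direction among genes past the threshold or, where none passes, the 5 of that direction with the smallest unadjusted p, each with a symbol, an average log2 CPM of 1 or more and both libraries of a group above both of the other. From each list it takes up to 4 members with the smallest p and an average log2 CPM of 1 or more. Other genes are said to be chosen after their values were seen. A gene and a list fixed beforehand are not reported here.

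The tests were checked on simulated counts with the means and library sizes of these samples, in which 200 genes were changed, 50 at each of 4 sizes. Changed genes were drawn from those with an average log2 CPM of 1 or more. With 1 trend of spread for all genes, the quasi-likelihood test ran on 14051 genes and recovered 8% of 2-fold, 78% of 4-fold, 92% of 8-fold and 100% of 16-fold changes, with 5 unchanged genes among 144 calls. DESeq2 then had 27 unchanged genes among 173 calls and edgeR's likelihood ratio test 8 among 149. In the other setting each gene's spread was the trend times a random factor, drawn with the fit's 3.20 prior degrees of freedom. Spreads drawn this way lie above the trend on average, so this setting is noisier than the fitted trend. On 13908 genes the quasi-likelihood test then recovered 0% at each size, and so did limma-voom. DESeq2 recovered 6%, 64%, 82% and 92% on 14346 genes, with 191 unchanged genes among 313 calls, and edgeR's likelihood ratio test had 118 unchanged among 221. A simulated list of 30 genes shifted by 1 on the log2 scale had, with 1 trend of spread, an adjusted p of 2.6e-26 with the preset correlation, 0.167 with an estimated correlation and 0.00393 with fry. With genes differing in spread these were 1.8e-14, 0.416 and 0.251, and 0 of 25 unshifted lists were called in either setting. The estimated correlation thus missed the shifted list in either setting. Simulated genes were drawn independently of each other. Members of the real lists moved together, with an estimated correlation of 0.896 for S phase and 0.932 for G2/M. The simulation therefore cannot show how often the preset correlation gives false calls for such lists.

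Alternatives listed before the data were examined were RLE, upper-quartile and total-count scaling, no filter and a stricter filter on low counts (1 CPM or more in each group's mean and 10 counts on average), DESeq2 1.42.0, limma-voom, edgeR with robust fitting, other thresholds, the code letter shared by 1 high and 1 low library as a covariate, leaving out the 20 genes with the most counts and the mitochondrial genes, and leaving out each library in turn. With a library left out its group has 1 sample, which is assumed to vary like the other group. The edgeR likelihood ratio test, edgeR's newer quasi-likelihood fit and DESeq2 with each library left out were added after seeing the data. The labels give no replicate numbers, animals or batches, so the code letter, which puts 1 high and 1 low library together, was the only block fitted. It also puts the remaining libraries, with the letters Q and S, together, although they share no letter. The block thus equals a pairing by replicate number, and it leaves fewer residual degrees of freedom than the 2 of the main fit. Plots were drawn with matplotlib from the tables.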

Results

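RNA sequencing was used to measure gene expression in granulosa cells, the somatic cells that line the ovarian follicle and surround the oocyte, from porcine antral follicles. Cell cycle phases had been read by flow cytometry, and the remaining cells were assigned to groups by the share of cells in G0/G1, the part of the cycle before DNA synthesis. The table analysed holds 4 libraries, 2 from cells with a high G0/G1 share and 2 from cells with a low share. The total count was 30399863 in high replicate 1, 28701688 in high replicate 2, 32674921 in low replicate 1 and 27442850 in low replicate 2, and between 17595 and 18205 genes had a count in a library. Levels are given in CPM, the count relative to the library total after scaling. A count of 0 allows a level of up to 0.0918 to 0.109 CPM, depending on the library. These limits are relative to the library totals before scaling. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

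The comparison of high with low G0/G1 cells asks which genes go with a larger share of cells in G0/G1. The labels do not say that these cells were arrested. The study's title names FOXO1, TP53INP1 and CDKN1A among the genes of a path to a halted cell cycle under hypoxia. Genes of DNA synthesis and mitosis were lower in the high G0/G1 libraries. Of genes induced by hypoxia 25 of 37 were lower, 12 of them among 13 that act in glycolysis or glucose uptake. Of 21 tested targets of FOXO transcription factors 18 were higher. With an estimated correlation between genes the camera test called none of these lists, though it also missed a list that was shifted in simulation. The separation between groups was wide for genes picked by their small unadjusted p, all of which missed the threshold after adjustment. ADAMTSL1, a secreted protein related to the ADAMTS proteases, had 105 ± 9.94 CPM (SD, n = 2) in high and 6.87 ± 1.37 in low G0/G1 cells, and SCUBE3, a secreted cell-surface glycoprotein, had 2.84 ± 0.685 in high and 86.4 ± 17.1 in low. IRS2, an adaptor of the insulin receptor, stood at 154 ± 15.3 CPM in high against 35.4 ± 2.15 in low, and GJA5, the gap junction protein connexin 40, at 1.31 ± 0.527 against 43.1 ± 5.98.

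Of 14352 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower in high G0/G1 cells at an adjusted p under 0.05, and the smallest adjusted p was 0.125. At an unadjusted p under 0.05 there were 2977 genes, 1424 higher and 1553 lower, against 717.6 expected by chance. DESeq2 called 754 genes higher and 711 lower on the same counts, while limma-voom called 0 in either direction with 3124 genes at an unadjusted p under 0.05. In simulated counts 200 genes were changed, and each gene's spread was drawn at random, on average above the fitted trend. The quasi-likelihood test then recovered 0% of 16-fold changes, and 61.0% of DESeq2's calls were genes simulated without a change. With 1 trend of spread for all genes these values were 100% and 15.6%. Such shares depend on how many genes were changed, so they do not give the share among the calls on the data. Without high replicate 1, the quasi-likelihood test called 363 genes higher and 591 lower. DESeq2 then called 954 and 1270, and without high replicate 2, low replicate 1 and low replicate 2 it called 380 and 469, 296 and 116, and 198 and 146. Both high libraries lay above both low ones in 3850 genes and below them in 4274, together 56.6% of the genes tested, where chance gives 33.3%. That share is an average over the ways to pair the libraries, so at least 1 pairing always reaches it. Genes also move together, so the excess does not measure how unlikely this grouping is.

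The 5 genes with the smallest unadjusted p in each direction all missed the threshold, at an edgeR adjusted p of 0.125. Higher in high G0/G1 cells were ADAMTSL1 by 3.93 ± 0.27 on the log2 scale (SE), SHROOM1, which organises the actin cytoskeleton, by 2.97 ± 0.23, TCP11L2 by 2.66 ± 0.24, GLDN, which encodes gliomedin, by 2.57 ± 0.24 and IRS2 by 2.12 ± 0.21. On the lower side, the log2 fold change was -4.93 ± 0.33 for SCUBE3, -5.05 ± 0.39 for the cyclic nucleotide-gated channel subunit CNGA3, -5.03 ± 0.40 for GJA5, -2.94 ± 0.28 for the calcium-binding protein TESC and -2.53 ± 0.24 for the metalloprotease ADAMTS17. DESeq2's adjusted p for these 10 genes ran from 2.7e-36 for SCUBE3 to 8.6e-11 for IRS2.

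Among the genes of the study's title, FOXO1 and TP53INP1 were higher in both high G0/G1 libraries, with little spread between them. FOXO1 (chromosome 11, 15317222 to 15410059 in Sscrofa11.1), a forkhead transcription factor held out of the nucleus by insulin and AKT signalling, stood at 1414 ± 10.8 CPM (SD, n = 2) in high and 574 ± 131 in low G0/G1 cells. TP53INP1 (chromosome 4, 41747654 to 41766688), a stress-induced nuclear protein, stood at 50.1 ± 0.305 and 17.7 ± 2.54 CPM. CDKN1A (chromosome 7, 32354776 to 32363771), which encodes the cyclin-dependent kinase inhibitor p21, had 129 ± 39.8 CPM in high and 47.8 ± 35.5 in low, with 101 and 158 CPM in the high libraries and 72.9 and 22.6 in the low ones. HIF1A (chromosome 1, 190625436 to 190673926), the oxygen-regulated subunit of hypoxia-inducible factor, overlapped between groups at 1004 ± 330 and 833 ± 219 CPM.

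**Figure D1:**
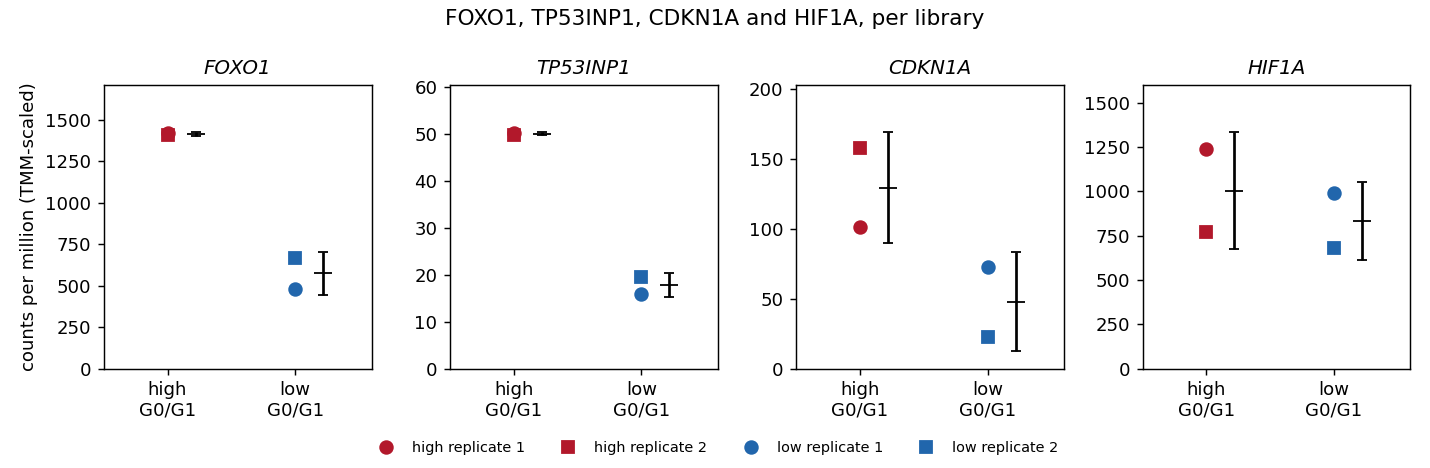
Expression of FOXO1, TP53INP1, CDKN1A and HIF1A in CPM (vertical axis, from 0) in each library, with circles for replicate 1, squares for replicate 2 and bars for the group mean with its SD (n = 2 per group). FOXO1 and TP53INP1 lie close together in the high libraries, at 1422 and 1407 CPM and at 50.3 and 49.9 CPM, and HIF1A overlaps between the groups.

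The log2 fold changes of these genes, each from edgeR's quasi-likelihood test, all missed the threshold after adjustment. They were 1.30 ± 0.26 for FOXO1 (SE, adjusted p = 0.155), 1.50 ± 0.23 for TP53INP1 (adjusted p = 0.130), 1.44 ± 0.59 for CDKN1A (adjusted p = 0.252) and 0.27 ± 0.34 for HIF1A (adjusted p = 0.687). DESeq2 called FOXO1 (adjusted p = 6.9e-04) and TP53INP1 (adjusted p = 4.5e-05), and gave an adjusted p of 0.102 for CDKN1A and 0.733 for HIF1A. With 1 library left out the log2 fold change of TP53INP1 ranged from 1.42 to 1.67, and that of HIF1A was -0.12 without high replicate 1. That of CDKN1A was 2.58 without low replicate 1 and 0.85 without low replicate 2.

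Genes of the S phase, in which DNA is copied, were lower in high G0/G1 cells in all 47 members tested, with a median log2 fold change of -1.88. FEN1, the flap endonuclease that processes Okazaki fragments, had 27.1 ± 2.04 CPM (SD, n = 2) in high and 90.4 ± 8.52 in low, and the replicative helicase subunits MCM7 and MCM5 had log2 fold changes of -1.51 ± 0.23 (SE) and -1.88 ± 0.36. RPA2, a subunit of the single-stranded DNA binding protein RPA, had -1.60 ± 0.29. Adjusted over the list alone 24 members fell and 0 rose, and over all genes tested 0 passed, while DESeq2 called 30 lower. All 60 tested members of the G2/M list, which act in mitosis and the phase before it, were lower too, with a median of -1.86. Examples were TMPO (-2.56 ± 0.45), a protein of the nuclear lamina, the mitotic kinase gene PLK1 (-2.48 ± 0.65), the condensin subunit NCAPD2 (-1.91 ± 0.52) and CKS1B (-1.26 ± 0.29), a partner of cyclin-dependent kinases. Of these 60, 0 passed either adjusted over the list alone or over all genes, while 35 had an unadjusted p under 0.05 and DESeq2 called 29 lower.

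By limma's camera test with its preset correlation, the adjusted p was 1.2e-24 for the S phase list and 6.4e-24 for the G2/M list, and each was 0.880 with an estimated correlation. The groups were made by their share of cells in G0/G1, so lower levels of these genes are what the grouping selects for. High replicate 1 lay between the other high library and the low ones. Its members of the S phase list were on average 0.18 below their mean over the 4 libraries on the log2 scale (-0.18), against -1.89 in high replicate 2, 1.15 in low replicate 1 and 0.92 in low replicate 2, and for G2/M the values were -0.03, -2.03, 1.09 and 0.98. Without high replicate 1 the counts adjusted over the list alone were 45 of 47 for S phase and 60 of 60 for G2/M, and without high replicate 2 they were 37 and 47. They were 0 and 1 without low replicate 1, and 0 and 0 without low replicate 2. DESeq2 called 1 and 2 members lower without low replicate 1, 14 and 4 without low replicate 2, 45 and 59 without high replicate 1, and 27 and 29 without high replicate 2. The medians were -1.64 and -1.71 without low replicate 1, -2.04 and -1.93 without low replicate 2, -3.13 and -3.38 without high replicate 1, and -1.35 and -1.11 without high replicate 2. With 1 library left out PLK1 ranged from -3.79 to -1.80 and NCAPD2 from -2.89 to -1.34.

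Inhibitors of the cell cycle went both ways. Of 8 tested members of the list of cyclin-dependent kinase inhibitors and pocket proteins, 5 were higher and 3 lower in high G0/G1 cells, with a median log2 fold change of 0.23, although the camera test pointed downwards (adjusted p = 0.828). CDKN1B, the gene of p27, stood at 88.9 ± 1.50 CPM (SD, n = 2) in high and 54.3 ± 2.15 in low, while CDKN2C, the gene of p18, stood at 33.1 ± 8.25 and 86.7 ± 12.6 CPM. Adjusted over the list alone 1 member passed, CDKN2C, which fell by 1.39 on the log2 scale, and this call was lost without high replicate 2 and without low replicate 2, each with 0 members lower. The counts were 1 higher and 3 lower without high replicate 1, and without low replicate 1 they were 1 and 1. The median was -0.07 without low replicate 2. CDKN2D had a log2 fold change of -1.48 ± 0.57 (SE), which ranged from -2.56 to -0.88 with 1 library left out.

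Targets of FOXO transcription factors were higher in high G0/G1 cells in 18 of 21 tested members, with a median log2 fold change of 1.28. Beside IRS2, the genes with the smallest p were SESN1 (1.78 ± 0.25, SE), a sestrin that restrains mTORC1, PIK3IP1 (3.62 ± 0.61), an inhibitor of phosphatidylinositol 3-kinase, and CCNG2 (1.03 ± 0.23), an atypical cyclin of resting cells. SESN1 stood at 51.6 ± 9.32 CPM (SD, n = 2) in high and 15.0 ± 1.36 in low. Adjusted over the list alone 8 members rose and 0 fell, the other 4 being GABARAPL1, CDKN1B, RICTOR and SESN3, of which RICTOR and SESN3 are named after their values were seen. Over all genes tested 0 passed, and DESeq2 called 9 higher. The camera test gave an adjusted p of 1.0e-09 with its preset correlation and an adjusted p of 0.880 with an estimated correlation. The count adjusted over the list alone was 4 without high replicate 2, 4 without low replicate 2 and 13 without high replicate 1. DESeq2's count was 6 without high replicate 2 and 3 without low replicate 2.

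Genes induced by hypoxia were lower in high G0/G1 cells in 25 of 37 tested members, with a median log2 fold change of -1.09. LDHA, which turns pyruvate into lactate, stood at 158 and 78.5 CPM in the high libraries and at 981 and 578 in the low ones. The glycolytic enzyme genes PGAM1 (-1.48 ± 0.26, SE) and ALDOC (-2.05 ± 0.38) and the collagen prolyl hydroxylase gene P4HA2 (-1.75 ± 0.28) were also lower. Adjusted over the list alone 17 members fell and 3 rose, and over all genes tested 0 passed, while DESeq2 called 16 lower and 3 higher. The 3 that rose, named after their values were seen, were EGLN1 (1.90 ± 0.53), an oxygen sensor that marks HIF1A for degradation, the MYC antagonist MXI1 (1.73 ± 0.41) and the peptide hormone gene ADM (1.15 ± 0.31). Among 13 members that act in glycolysis or glucose uptake 12 were lower, with a median of -1.48, and among the other 24 members 13 were lower, with a median of -0.14, a division made after the values were seen.

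**Figure D2:**
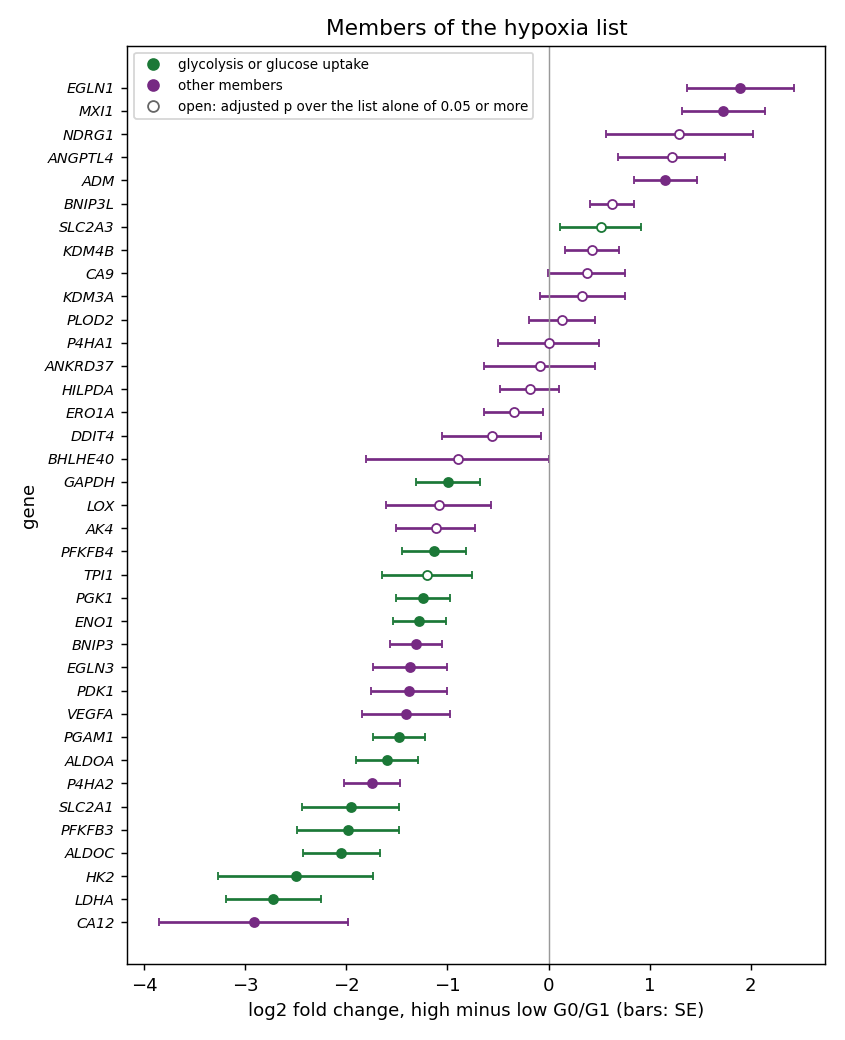
Log2 fold change of high over low G0/G1 cells (horizontal axis, bars are SE, n = 2 per group) for the 37 tested members of the hypoxia list, with glycolysis and glucose uptake in green, other members in purple, and open points for members that missed the threshold adjusted over the list alone. Of the 13 green points 12 lie below 0, and SLC2A3 lies above it at 0.52.

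The camera test on the hypoxia list gave an adjusted p of 9.3e-05 with its preset correlation and an adjusted p of 0.880 with an estimated correlation. On average its members were highest in low replicate 1, at 0.61 above their mean on the log2 scale, against 0.06 in low replicate 2, -0.34 in high replicate 1 and -0.33 in high replicate 2. The count adjusted over the list alone was 0 lower without low replicate 1 and 7 lower without high replicate 2, and the count higher was 0 when either low library was left out and 1 without high replicate 2. DESeq2 called 1 lower and 1 higher without low replicate 1, 7 and 0 without low replicate 2, and 12 and 1 without high replicate 2. The list's adjusted p was 0.0162 without low replicate 1 and 1.9e-04 without high replicate 2.

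Genes of granulosa cell identity and oestradiol synthesis changed in both directions. The list's aromatase gene, CYP19A1, had 0 counts in each library and was not tested. Most aromatase reads were counted for its paralog CYP19A3, which is not on the list. FSHR, the receptor of follicle-stimulating hormone, stood at 24.3 ± 2.53 CPM (SD, n = 2) in high and 83.7 ± 3.02 in low G0/G1 cells, and IHH, a hedgehog ligand through which granulosa cells signal to theca, at 7.52 ± 6.82 and 403 ± 47.9. AMHR2, a receptor of anti-Müllerian hormone, stood at 73.3 ± 23.6 against 28.5 ± 3.20 CPM, and GJA1, which encodes connexin 43, at 5154 ± 2293 against 1613 ± 3.50. Adjusted over the list alone of 20 tested members, AMHR2 and GJA1 rose and FSHR and IHH fell, while 0 passed over all genes tested and DESeq2 called 2 higher and 3 lower, with 1 and 7 without high replicate 1, 4 and 3 without high replicate 2, and 0 and 2 without either low library. The list had a median log2 fold change of -0.63 (camera adjusted p = 0.0980), and its adjusted p was 0.00231 without high replicate 1 and 0.0470 without low replicate 1, and its median was -0.37 without high replicate 2 (adjusted p = 0.359). When either low library was left out, 0 members were called higher adjusted over the list alone, and without high replicate 1 8 were called lower.

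Genes of progesterone synthesis and luteinisation had a median log2 fold change of 0.12 (camera adjusted p = 0.571), with 11 of 16 tested members higher. LHCGR, the receptor of luteinising hormone, stood at 1001 and 277 CPM in the high libraries against 148 and 95.5 in the low ones, and PTGFR, a prostaglandin receptor gene, had a log2 fold change of 1.39 ± 0.32 (SE). In the list of the ovulatory response 11 of 18 members were higher, with a median of 0.81 (camera adjusted p = 0.0934), among them the EGF-like ligand gene BTC (3.22 ± 1.05), PLAUR (1.75 ± 0.50), the urokinase receptor, and the coregulator gene NRIP1 (1.55 ± 0.44). With 1 library left out these ranged from 1.87 to 4.99, 1.04 to 2.21 and 0.88 to 2.00. Cholesterol biosynthesis had a median of 0.35 (camera adjusted p = 0.465), with HMGCS1 higher (1.22 ± 0.30) and DHCR7 lower (-1.13 ± 0.35). In each of these 3 lists 0 members passed over all genes or adjusted over the list alone with all 4 libraries, while 2, 3 and 6 had an unadjusted p under 0.05 and DESeq2 called 2, 3 and 2 higher. DESeq2 called 3 higher and 3 lower, 6 and 1, and 0 and 1 without high replicate 1, and 3, 1 and 5 higher without high replicate 2. It called 1 higher and 2 lower, 5 and 0, and 1 and 0 without low replicate 1, and 0, 1 and 0 higher without low replicate 2. Without high replicate 1, 5 ovulatory genes rose and 1 fell adjusted over the list alone, and without high replicate 2, 5 cholesterol genes and 1 ovulatory gene rose. Without low replicate 1, 2 ovulatory genes and 1 cholesterol gene rose. In the progesterone list 1 rose and 2 fell without high replicate 1, 2 rose without high replicate 2 and 1 fell without low replicate 1. Without high replicate 2 the adjusted p was 0.0228 for the progesterone list and 6.9e-04 for cholesterol biosynthesis, with a median of 0.79 for the latter. Without low replicate 1 cholesterol biosynthesis had an adjusted p of 0.0256 with a median of 0.59, and the progesterone median was 0.66 (adjusted p = 0.529). The progesterone median was 0.28 without low replicate 2 (adjusted p = 0.759). Without high replicate 1 the medians turned to -0.17 for cholesterol biosynthesis (adjusted p = 0.676), with 13 of 21 members lower, and to -0.31 for the progesterone list (adjusted p = 0.931), with 9 of 16 lower. The ovulatory list had an adjusted p of 0.0152 without high replicate 1, 0.0119 without low replicate 1 and 0.0184 with the code letter of the labels as a covariate. Without high replicate 2 its median was 0.07 (adjusted p = 0.503), and without low replicate 2 it was 0.44 (adjusted p = 0.208).

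The follicular extracellular matrix held genes in both directions. COL18A1, a basement membrane collagen, stood at 8.89 ± 3.27 CPM (SD, n = 2) in high and 70.1 ± 1.39 in low G0/G1 cells. TIMP3 (1.95 ± 0.35, SE), an inhibitor of metalloproteases, AGRN (1.10 ± 0.21), which encodes agrin, and the basement membrane collagen gene COL4A2 (1.18 ± 0.24) were higher. Of 23 members 6 rose and 2 fell adjusted over the list alone, and over all genes tested 0 passed. The list as a whole had a median log2 fold change of 0.00 (camera adjusted p = 0.599), and medians from -0.03 to 0.62 with 1 library left out, the highest without low replicate 2 (adjusted p = 0.212). The count called higher was 0 without low replicate 1, 0 without low replicate 2 and 2 without high replicate 2, and the count called lower was 1 without low replicate 2 and 3 without low replicate 1 or high replicate 1. DESeq2 called 7 higher and 3 lower, against 1 and 3 without low replicate 1, 1 and 1 without low replicate 2, and 4 and 2 without high replicate 2.

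Autophagy genes were higher in high G0/G1 cells in 18 of 22 tested members, with a median log2 fold change of 0.51. ATG14 (1.13 ± 0.23, SE) and ATG13 (1.12 ± 0.28), which start the autophagosome, the cargo receptor gene SQSTM1 (1.16 ± 0.31) and GABARAPL1 (1.97 ± 0.53), an ATG8 family member, had the smallest p. The camera test gave an adjusted p of 0.00306, and an adjusted p of 0.880 with an estimated correlation. Nuclear-encoded genes of oxidative phosphorylation were lower in 24 of 27 tested members, with a median of -0.37 and an adjusted p of 0.00332, again with an adjusted p of 0.880 with an estimated correlation. NDUFB8 (-0.62 ± 0.19), NDUFV2 (-0.62 ± 0.21) and NDUFB10 (-0.64 ± 0.22) of complex I and ATP5G1 (-0.94 ± 0.29) of ATP synthase were examples. In both lists 0 members passed over all genes or adjusted over the list alone, while 9 autophagy and 8 oxidative phosphorylation members had an unadjusted p under 0.05 and DESeq2 called 5 and 0. Without high replicate 1, 8 autophagy members passed adjusted over the list alone. Without high replicate 2 the autophagy median was 0.14, with 14 of 22 members higher (adjusted p = 0.0369). DESeq2 called 2 autophagy members without high replicate 2, 2 without low replicate 1 and 0 without low replicate 2.

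Immediate early genes, which respond within minutes to stimuli that include tissue handling, were higher in all 20 members, with a median log2 fold change of 0.84. EGR1 stood at 1524 ± 234 CPM (SD, n = 2) in high and 567 ± 230 in low, and EGR2 (1.91 ± 0.43, SE), KLF6 (1.82 ± 0.54) and JUNB (2.00 ± 0.74) were among them. JUNB stood at 116 and 426 CPM in the high libraries against 95.7 and 39.5 in the low ones, and with 1 library left out it ranged from 0.78 to 2.85 and KLF6 from 1.26 to 2.87. The camera test gave an adjusted p of 9.3e-05, an adjusted p of 0.880 with an estimated correlation, and an adjusted p of 0.0538 without low replicate 2. Members lay lowest in that library, at -1.03 from their mean against 0.04 in low replicate 1. The median was 0.47 without low replicate 2 and 1.69 without low replicate 1. In this list 0 members passed over all genes or adjusted over the list alone, against 5 at an unadjusted p under 0.05 and 4 called by DESeq2, and 3 passed adjusted over the list alone without low replicate 1. DESeq2 called 0 without low replicate 2 and 7 without high replicate 1.

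The remaining stress lists were not called by the camera test without a covariate in all 4 libraries. Endoplasmic reticulum stress had a median log2 fold change of 0.48 (adjusted p = 0.0822), with the transcription factor gene XBP1 at 529 ± 107 CPM (SD, n = 2) in high and 221 ± 83.7 in low, and the list lay at -0.86 in low replicate 2. Its adjusted p was 0.0435 with the code letter of the labels as a covariate and 7.4e-09 without low replicate 1, with a median of 1.11. Without low replicate 2 the median turned to -0.04, with 12 of 20 members lower (adjusted p = 0.914), and without high replicate 2 it was 0.26 (adjusted p = 0.133). Apoptosis had a median of -0.01 (adjusted p = 0.807), and of -0.14 to 0.03 with 1 library left out, with the proapoptotic genes BID (-1.10 ± 0.30, SE) and DIABLO (-0.70 ± 0.20) lower and BMF (2.40 ± 0.72) higher. BMF stood at 4.80 and 18.4 CPM in the high libraries, and its log2 fold change ranged from 1.13 to 3.05 with 1 library left out. The interferon response had a median of -0.12 (adjusted p = 0.599), which was 0.23 without low replicate 2 (adjusted p = 0.979), -0.55 without high replicate 2 (adjusted p = 0.441) and -0.41 without low replicate 1 (adjusted p = 0.176). Heat shock genes had one of -0.31 (adjusted p = 0.406), which was -0.76 without low replicate 2 (adjusted p = 5.4e-04) and turned to 0.33 without low replicate 1, with 9 of 13 members higher (adjusted p = 0.154). Mitochondrially encoded genes had a median of -0.37 (adjusted p = 0.183), which was -0.79 without high replicate 1 (adjusted p = 0.0677) and -0.73 without low replicate 2 (adjusted p = 6.0e-07), and turned to 0.07 without low replicate 1, with 8 of 12 members higher (adjusted p = 0.924). Cytoplasmic ribosomal proteins had a median of -0.15 (adjusted p = 0.162), which was -0.31 without high replicate 2 (adjusted p = 0.00173) and -0.02 without high replicate 1 (adjusted p = 0.931), and -0.08 without low replicate 2 (adjusted p = 0.563). Their adjusted p was 0.0439 with no filter on low counts. In these 6 lists 0 members passed over all genes or adjusted over the list alone with all 4 libraries, and 9 members of the endoplasmic reticulum stress list rose adjusted over the list alone without low replicate 1. An unadjusted p under 0.05 was reached by 5 endoplasmic reticulum stress, 4 apoptosis and 3 interferon genes and by 0 in the other 3 lists. DESeq2 called 4, 2 and 2, and 0 in the other 3. Its count for endoplasmic reticulum stress was 7 without low replicate 1, 1, a lower gene, without high replicate 2 and 0 without low replicate 2, and for apoptosis 0 in each of these and 8 without high replicate 1. In the apoptosis list 2 genes rose and 2 fell without high replicate 1, and without low replicate 2, 2 mitochondrially encoded genes fell. Mitochondrially encoded genes took 1.65% of the counts in high replicate 1 (95% Wilson interval 1.64% to 1.65%), 1.36% in high replicate 2 (1.36% to 1.36%), 2.11% in low replicate 1 (2.10% to 2.11%) and 1.89% in low replicate 2 (1.88% to 1.89%), intervals that cover counting error only.

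Markers of other cell types differed more between the 2 low libraries than between the groups. The collagen genes COL1A1, COL1A2 and COL3A1, abundant in fibroblasts, stood at 390, 454 and 478 CPM in low replicate 2, and at no more than 34.3, 25.3 and 36.9 CPM in the other libraries. Members of the list of fibroblasts and smooth muscle lay on average at 2.30 on the log2 scale from their mean in low replicate 2, against -1.62 in low replicate 1, -0.81 in high replicate 1 and 0.13 in high replicate 2. CYP17A1, the androgen-producing enzyme of theca cells, had 1485 counts in low replicate 2 and at most 29 in another library. INSL3, on the theca list, was at 23.8 ± 8.79 CPM (SD, n = 2) in the high libraries, 75.3 in low replicate 1 and 260 in low replicate 2.

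Between the groups, none of these lists was called with all 4 libraries and no covariate. The median log2 fold change was -1.86 for fibroblasts and smooth muscle (camera adjusted p = 0.183), -0.88 for endothelium (0.632), -0.41 for theca cells (0.632), 0.19 for leukocytes (0.828), -1.04 for the ovarian surface and other epithelium (0.104) and 0.92 for the 3 tested erythroid genes (0.725). The 1 tested oocyte gene, GDF9, had a log2 fold change of 0.01 ± 0.40 (SE), and of -0.28 to 0.51 with 1 library left out. In each of them 0 members passed over all genes or adjusted over the list alone with all 4 libraries, and 10 members of the list of fibroblasts and smooth muscle fell adjusted over the list alone without low replicate 1. An unadjusted p under 0.05 was reached by 3 theca genes and 1 epithelial gene, and DESeq2 called these numbers and 1 gene of fibroblasts and smooth muscle, with 8 of the latter lower without low replicate 1 and 3 higher without low replicate 2. Of theca genes 1 rose and 3 fell without high replicate 1, 1 rose without high replicate 2 and 2 fell without low replicate 1, and of endothelial genes 1 fell without low replicate 1. With 1 library left out the medians ranged from -2.50 to 1.50 for fibroblasts and smooth muscle, -1.95 to 1.63 for endothelium, -0.99 to -0.25 for theca cells, -0.68 to 2.20 for leukocytes, -3.17 to -0.04 for epithelium and 0.50 to 1.35 for erythroid genes. Without low replicate 2 the median turned to 1.50 for fibroblasts and smooth muscle (adjusted p = 3.2e-04) and to 1.63 for endothelium (adjusted p = 0.00861), and leukocytes had an adjusted p of 0.00710. Without low replicate 1 fibroblasts and smooth muscle had an adjusted p of 1.3e-23, endothelium 9.0e-07, theca cells 9.1e-04, epithelium 0.00224, and leukocytes, now lower, 0.0261. Without high replicate 2 it was 0.0347 for fibroblasts and smooth muscle and 0.00109 for epithelium. Epithelium had an adjusted p of 0.0287 with the code letter as a covariate, and its median was -0.27 without high replicate 1 (adjusted p = 0.931) and -0.04 without low replicate 2 (adjusted p = 0.563).

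**Figure D3:**
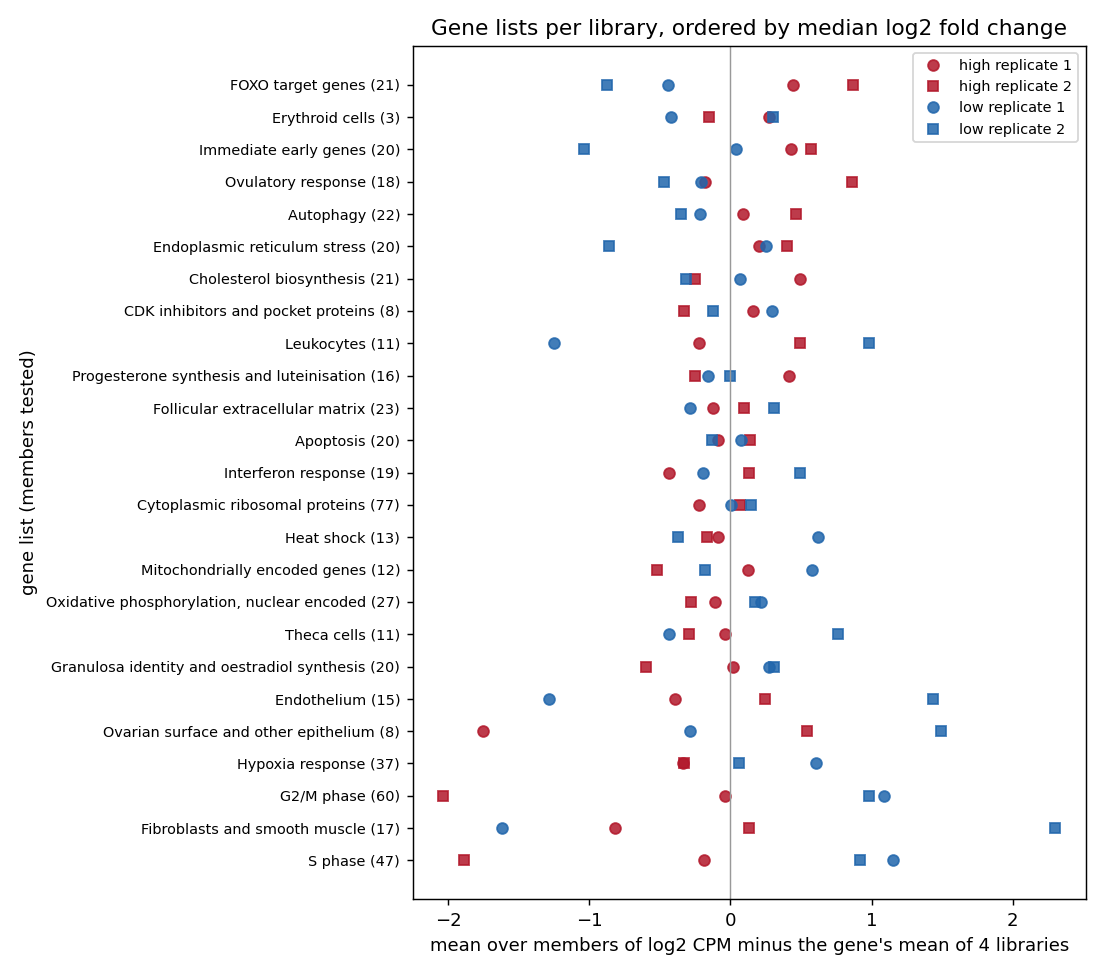
Mean over the tested members of each list of log2 CPM minus the gene's mean over the 4 libraries (horizontal axis), for gene lists ordered by their median log2 fold change, with high G0/G1 libraries in red, low in blue, circles for replicate 1 and squares for replicate 2. Low replicate 2 lies farthest to the right for fibroblasts and smooth muscle, at 2.30, and high replicate 2 farthest to the left for G2/M, at -2.03.

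Across all genes the libraries differed within groups as well as between them. Of all genes tested, 18.8% differed more than 2-fold between the high libraries and 12.5% between the low ones, against 21.2% to 32.3% across groups. Pearson's correlation of log2 CPM across genes, which are not independent replicates, was 0.944 between the high libraries, 0.958 between the low ones and 0.897 to 0.945 across groups. The first dimension of a multidimensional scaling held 45.9% of the variance and put high replicates 1 and 2 at -0.43 and -2.23 and the low ones at 1.63 and 1.03. The second, with 33.2%, put high replicate 2 and low replicate 2 at -0.33 and -1.93 and the others at 1.18 and 1.08. These 2 libraries share a code letter in the labels, whose meaning is not given in the sources used here.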

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

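The edgeR likelihood ratio test, edgeR's newer quasi-likelihood fit and DESeq2 in 3 libraries were chosen after seeing the data, the other alternatives before. The count of 0 genes higher and 0 lower stayed at 0 under the scalings, the stricter filter, robust fitting, limma-voom, the code letter covariate, the reduced composition, both other thresholds and the newer fit. No filter gave 2 higher (ADAMTSL1 and SHROOM1) and 3 lower (SCUBE3, CNGA3 and GJA5), DESeq2 754 and 711, and the likelihood ratio test 557 and 534. DESeq2 in 3 libraries gave 954 and 1270 without high replicate 1, 380 and 469 without high replicate 2, 296 and 116 without low replicate 1, and 198 and 146 without low replicate 2. Leaving out 1 library gave 0 to 363 higher and 0 to 591 lower with the quasi-likelihood test, and the non-zero counts came without high replicate 1. The cause of these differences was not tested on the data. In simulation with 200 changed genes and randomly drawn gene spreads, on average above the fitted trend, 61.0% of DESeq2's calls were unchanged genes. For the likelihood ratio test the share was 53.4%. With 1 trend of spread the shares were 15.6% for DESeq2 and 5.37% for the likelihood ratio test.

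The lists of S phase, G2/M, FOXO targets and hypoxia kept their direction in every alternative run and their side of the threshold in all but the other list tests. The adjusted p was 0.880 for each with an estimated correlation, and 0.610, 0.610, 0.459 and 0.610 with fry. With 1 library left out, the adjusted p of fibroblasts and smooth muscle ranged from 1.3e-23 to 0.931, endothelium from 9.0e-07 to 0.931 and leukocytes from 0.00710 to 0.898, with directions that turned. Among lists not called with all libraries, the code letter covariate gave an adjusted p of 0.0435 for endoplasmic reticulum stress, 0.0184 for the ovulatory response and 0.0287 for epithelium, and no filter 0.0439 for ribosomal proteins. Of 107 named genes, 61 were called by DESeq2, 55 by the likelihood ratio test, 36 without high replicate 1 and 5 with no filter. Log2 fold changes that turned with 1 library left out ranged from -0.12 to 0.62 for HIF1A, -1.43 to 0.61 for BAG3, -5.67 to 0.81 for LUM, -4.14 to 1.34 for COL1A2, -2.63 to 0.29 for ACTA2, -2.45 to 0.81 for ROBO4, -2.43 to 3.10 for CDH5, -1.37 to 1.66 for LAPTM5, -0.43 to 1.54 for CD74, -0.28 to 0.51 for GDF9, -1.69 to 0.93 for CDH1 and -1.72 to 0.0900 for ND1. With limma-voom the value was 0.33 for CDH5, 0.0488 for LAPTM5 and -0.35 for CDH1. It was -0.31 for CDH1 with the code letter covariate, and the log2 fold change of GDF9 was -0.0405 on library totals. The cause was not tested. At this depth a count of 0 allows a level of at most 0.109 CPM, relative to the library total before scaling.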

Other observations

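All tests weighed below were chosen after the results were seen, and the genes named in the first paragraphs were chosen after their values were seen. Several receptors and signalling genes outside the lists separated the groups. LGR4, a receptor that strengthens Wnt signalling, stood at 751 and 1107 CPM in the high G0/G1 libraries and at 132 and 158 in the low ones. The log2 fold change was 1.44 ± 0.22 (SE) for BMPR1B and 1.25 ± 0.21 for BMPR2, which encode receptors of bone morphogenetic proteins, and 2.94 ± 0.32 for the signal transducer SMAD9. The antioxidant regulator NFE2L2 had 1.45 ± 0.20, the glutathione transferase MGST1 3.32 ± 0.40 and the efflux pump ABCB1 3.19 ± 0.36, while IGFBP2, which binds insulin-like growth factors, had 1.63 ± 0.25. FOXO1's relatives FOXO3 and FOXO4 had 0.69 ± 0.24 and 1.10 ± 0.27. By edgeR's quasi-likelihood test, 0 of these genes passed at an adjusted p under 0.05, with values between 0.125 for LGR4 and 0.213 for FOXO3.

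More single genes had values below 0, all outside the lists except INHBB, a member of the list of granulosa identity and oestradiol synthesis. Log2 fold changes were -1.80 ± 0.26 (SE) for the phosphatase CDC25A, -1.82 ± 0.27 for the origin recognition subunit ORC6 and -1.97 ± 0.37 for the clamp loader subunit RFC4. The lactate exporter SLC16A3 had -3.25 ± 0.46, with 36.1 and 20.6 CPM in the high libraries and 355 and 186 in the low ones, and the phosphofructokinase PFKP had -2.31 ± 0.30. INHBB, the beta B subunit of inhibin and activin, stood at 1492 and 557 CPM in the high libraries and 3654 and 3023 in the low ones. Each missed the edgeR threshold, at adjusted p values between 0.125 for SLC16A3 and 0.190 for INHBB. The aromatase paralog CYP19A3 had 118837, 44131, 46047 and 32939 counts in high 1, high 2, low 1 and low 2, and CYP19A2 75, 30, 34 and 45, while CYP19A1 had 0 in each. The 3 are paralogs, and how the counting assigned any reads that they share is not known.

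The first pattern is that S phase and G2/M genes were lower in high G0/G1 cells. Against high replicate 2 alone carrying the difference, the median log2 fold change of the 107 tested members was -1.17 without that library, with 99.1% of members lower. Against cells of another type in low replicate 2, the median without low replicate 2 was -1.93, and -1.86 with all 4 libraries. A lower share of cycling cells is what the design selected, so lower levels of these genes go with the grouping itself and are not a separate result. No test here measures how much of the difference comes from other differences between the cells. The size of the difference came largely from high replicate 2, in which these genes were on average 1.87 lower on the log2 scale than in high replicate 1, itself 1.13 below the mean of the low libraries.

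The second pattern is that the 13 members of the hypoxia list that act in glycolysis or glucose uptake had a median log2 fold change of -1.48 in high G0/G1 cells. The division was made after the values were seen, and the unadjusted camera p of these 13 was 0.0991 with an estimated correlation. A weaker hypoxia response as a whole cannot be told apart from a difference in glycolysis alone, since the other 24 members went both ways, 13 lower and 11 higher, with a median of -0.14. Low replicate 1 does not carry the pattern alone, since the glycolysis median was -1.06 without it, and without low replicate 2, where other cell types may be present, it was -1.56. No biological explanation was tested for this pattern.

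The third pattern is that of 52 marker genes of other cell types, after leaving out 2 that granulosa lists also hold, 37 were highest in low replicate 2, against 24.3% of all genes tested, with 14 of 17 for fibroblasts and smooth muscle, 12 of 15 for endothelium, 7 of 11 for leukocytes and 4 of 9 for theca. Stroma, vessels and theca carried over at dissection are a candidate source that stays open. The count does not settle it, because it restates what drew attention to this library and genes of a list move together. By the count theca is less clear, but genes of its list that granulosa cells express have a baseline that can hide a rise. In that library COL3A1 had 478 CPM, CDH5 6.21 and CYP17A1 51.5. STAR and HSD3B1, of the progesterone list and named after their values were seen, had 39.5 and 27.1 CPM there. In the other libraries they had at most 9.63 and 2.00 CPM. The progesterone list as a whole lay at 0.00 from its mean in low replicate 2. No sort or gate that would remove cells of other types is given for the RNA samples. A lower share of granulosa cells, raising every other type alike, was weighed by the log2 ratio of low replicate 2 to the other libraries. Genes needed 10 counts or more on average in those libraries, and the theca list was left out because granulosa cells express some of its genes. The median was 2.96 with a lower quartile of 2.10 over 16 genes of fibroblasts and smooth muscle. It was 1.50 with an upper quartile of 1.73 over 9 leukocyte genes, medians that differ by 1.46. Over 12 endothelial genes it was 2.08, with quartiles of 0.75 and 2.78. These ratios cannot decide the question, since they also depend on how much of each cell type the other libraries held. Leukocyte genes lay on average at 0.49 from their mean in high replicate 2, against 0.98 in low replicate 2. No biological explanation was tested for this pattern.

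The 4 libraries can be divided into pairs in 3 ways, too few for a share under 0.05. The real grouping gave 2977 genes at an unadjusted p under 0.05 with edgeR's quasi-likelihood test, the highest of the others 371, and 1 of the 3, the real one, gave as many as that.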
